A study of Mus musculus with 50 samples.

How the data were processed

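RNA was measured by RNA-seq of poly(A) RNA in differentiated mouse ES cells (wild type, RepB+/- and RepB-/-, 2 libraries each) and in MEF (wild type and RepB, 1 library each). Per the labels' protocols, the ES cells were grown on fibroblast feeders, freed of them, kept 4 days in suspension as embryoid bodies and 10 more days plated. Of 50 samples in the series, these 8 have processed RNA-seq tables and the other 42 were not analysed here. The 3 deposited tables (ES replicate 1, ES replicate 2 and MEF) hold 24 columns in all for 24391 genes, and give the authors' whole-number counts of reads per gene and library: all reads, reads given to the 129 allele and reads given to the CAST allele. The allele columns are headed mus and cas, and were taken as 129 and CAST from the strain background that the labels give for all 8 samples. Per the file headers, the tables have the column layout of featureCounts, with positions on mouse build mm9. Per the submitters' processing notes, the tools used in the series were Novoalign, SAMtools, bedtools, TopHat, featureCounts, cutadapt, HOMER and Juicer; versions, roles, the strand setting of the counting and the handling of reads that map to several places are not stated there. The counts were not normalized by the authors, as the values show: they are whole numbers with a different sum in each library. In no gene did 129 and CAST counts together exceed the count of all reads. The position of 1 exon is given for each gene, and it was used as the gene's position.

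Reads of genes with near-identical copies, such as ribosomal protein genes, may be split or dropped by such counting, and reads over a strain variant can map less well for the allele that differs from the reference, so 129 shares were read beside those of chromosome 13. Most autosomes of the ES cells showed almost only 129 reads (median 129 share over all autosomal genes 98.7%), and chromosome 13 had 97.4% of its genes with between 20% and 80% of reads from 129.

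Before the data were examined, the groups, the comparisons, the tests, the gene lists, the rule for named genes and all alternatives were fixed, except 2 alternatives and the tests of explanations that the closing section names as chosen later. The 6 ES libraries were fitted together with edgeR 4.0.16 in R 4.3.3: counts of all reads, filterByExpr (minimum count 10, minimum total 15), TMM scaling and the quasi-likelihood F-test with genotype as the only term. The fit gave a common biological coefficient of variation of 9.50%. Genes were called at a Benjamini-Hochberg adjusted p of 0.05 over all 15149 genes tested, and for fixed lists also adjusted over the list alone. Lists of at least 3 tested genes were compared with all other genes by camera of limma 3.58.1 with a preset correlation between genes of 0.01 (adjusted over the lists of a comparison), and again with the correlation estimated from the data, under which no list was called in any of the 3 comparisons. The 20 lists were: X inactivation centre, escape genes, X genes subject to silencing, PRC2 subunits, PRC1 subunits, Hox genes, pluripotency, cardiac muscle, neural, endoderm and yolk sac, fibroblast and mesenchyme, endothelium, blood, epithelium, imprinted genes, proliferation, p53 targets, immediate early and stress, Y-linked and mitochondrially encoded. Genes were named by rule: the 10 called genes that rose most and the 10 that fell most among genes with a mean of at least 5 CPM and no overlap between the libraries compared, up to 4 called genes per list with the lowest adjusted p (2 with the lowest p if none was called), the 5 X-linked genes most significant in each direction, the 6 leading allelic shifts each way with the escape and silenced lists, in MEF the 8 highest and 8 lowest ratios among genes with at least 200 reads and the fixed lists, and Xist. The 5 MEF genes whose allelic intervals lay apart, the X-linked genes that stayed low and the stretch of chromosome 16 fall outside this rule and were chosen after their values were seen.

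For allelic reads, genes averaging at least 20 allelic reads per library were kept (11597 in ES cells). The share of 129 reads per library is the median over genes of 129 counts over the sum of 129 and CAST counts. Genotypes were compared by an exact two-sided permutation test of the library values. Per gene, edgeR tested the change in the ratio of 129 to CAST reads, with library as a block and an allele-by-genotype term. Levels of each allele used CPM with a pseudocount of 0.05. For MEF, log2 ratios of TMM-scaled CPM with a prior count of 2 were taken for genes averaging at least 1 CPM, with no test, and a list's median was placed among 10000 random lists of equal size matched on expression in 20 bins. Intervals are 95%: exact Clopper-Pearson for shares and for ratios of counts, and order statistics for medians. Where a library had 0 counts, a floor of 3 counts per library was used. No molecular identifiers are stated, so intervals and floors cover counting error only. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

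Total counts per library ran from 8000722 to 28045645, and allelic counts were between 26.7% and 27.99% of them. Replicates differed by more than counting error, with a chi-square per degree of freedom of 6.88 in wild type, 15.2 in RepB+/- and 13.1 in RepB-/-. The steps were tested on simulated data with known changes in 200 genes. For RepB+/- against wild type 56.7% of 1.5-fold, 83.6% of 2-fold and 92.4% of 4-fold changes were recovered, with 14 false calls among 14969 genes. For RepB-/- against wild type these were 53.7%, 82.1% and 95.5%, with 14 false calls among 14966 genes, and for RepB-/- against RepB+/- 50.8%, 74.6% and 97.0%, with 11 among 14965. Allelic shifts of 1, 2 and 3 on the log2 scale were recovered in 34.3%, 68.7% and 87.9% of genes for RepB+/- (0 false calls among 11518 genes) and in 29.9%, 65.7% and 87.9% for RepB-/- (3 among 11512). A 1.25-fold change of all X-linked genes was called in each of the 3 comparisons, and the list test made 0, 1 and 2 false calls when random genes were changed. The simulated genes were drawn independently, so these false calls do not check the list test where genes correlate. In RepB+/- against wild type the estimated correlation was 0.11 for X-linked genes and 0.45 for pluripotency genes. In MEF libraries simulated once at each size, the 368 X-linked genes stood at percentile 5.15 when unchanged and at 100 when raised 1.1-fold.

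Alternatives tried were DESeq2 1.42.0 with its own size factors, other scalings, no filter and a stricter one, only the libraries compared, the replicate number as a block, an estimated correlation, leaving out each library, other minimums of allelic reads, pooled reads, a correction for reference bias, and for MEF other prior counts, filters and scaling.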

Results

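Poly(A) RNA was sequenced from 6 libraries of mouse embryonic stem (ES) cells differentiated in culture and from 2 libraries of mouse embryonic fibroblasts (MEF). The ES cells came from a cross of CAST/Ei and 129/Sv/Jae mice, so that reads over strain variants could be given to the CAST or to the 129 chromosome. They were wild type, heterozygous (RepB+/-) or homozygous (RepB-/-) for a deletion of Repeat B, a tandem repeat of the long non-coding RNA Xist, with 2 libraries per genotype, and were collected after 4 days as embryoid bodies and 10 further days on plates. The MEF libraries, 1 wild type and 1 RepB, have no replicates, and the labels do not say whether the RepB line lost the repeat on 1 or both alleles. Xist coats the inactive X chromosome and brings Polycomb complexes to it, and the comparisons ask how genes of that chromosome are expressed in RepB cells. For RepB+/- the sample titles do not say whether the 129 or the CAST copy of Xist lost the repeat. The other 42 samples of the series, which measured chromatin, chromosome contacts and RNA binding, were not analysed here.

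Total counts per ES library were 19676395 and 12505962 in wild type, 26782887 and 8000722 in RepB+/-, and 28045645 and 21649020 in RepB-/-. The MEF libraries held 12126941 (wild type) and 18631736 (RepB) counts. Between 26.7% and 27.99% of the counts of a library could be given to an allele. The first principal component of the ES libraries, with 50.8% of the variance, placed the wild-type libraries at -33.2 and -45.7 and the RepB libraries between 13.9 and 24.3. On the second component, with 23.6%, the shallowest library, RepB+/- replicate 2, stood at -39.3 while the others lay between -7.18 and 18.3. The labels do not say that the replicates are separate cultures, so the p-values measure the spread between these libraries.

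Xist, the RNA that silences the X chromosome it is made from, was abundant in every ES library, at 906 ± 5.30 CPM (counts scaled to library size; SD, n = 2) in wild type, 863 ± 76.3 in RepB+/- and 989 ± 227 in RepB-/-. Its log2 fold change against wild type was -0.07 (SE 0.16, edgeR adjusted p = 0.801) in RepB+/- and 0.13 (SE 0.16, adjusted p = 0.660) in RepB-/-, neither called. The gene lies on the minus strand of chromosome X, where the count table lists an exon from 100655712 to 100663375 (mm9) and 17918 bases of exon in all. Counts over the whole gene do not check a deletion inside it. Nearly all Xist reads came from the 129 chromosome in wild type (98.9% and 98.6%) and in RepB+/- (97.8% and 97.3%). In RepB-/- 10.8% and 12.8% of them came from the CAST chromosome, against 1.12% and 1.42% in wild type. The log2 ratio of 129 to CAST reads changed by -3.39 (SE 0.18, edgeR adjusted p = 6.19e-73) in RepB-/- and by -0.94 (SE 0.20, adjusted p = 0.000213) in RepB+/-, and the latter call was lost without wild-type replicate 1 (-0.76, adjusted p = 0.134). Tsix is transcribed across Xist from the other strand, and without a stated strand in the counting, reads of this pair cannot be told apart.

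In wild-type cells most X-linked reads came from the CAST chromosome, and in both RepB genotypes reads from the 129 chromosome, the source of most Xist reads in each ES library, were far more common. The median 129 share over 376 X-linked genes without Xist was 5.94% ± 0.897 (SD, n = 2) in wild type, 33.4% ± 3.36 in RepB+/- and 34.8% ± 0.983 in RepB-/-. Genes fixed in advance as subject to X inactivation had median shares of 6.80% ± 0.486, 34.0% ± 3.83 and 37.3% ± 0.269 in the same order. Genes fixed in advance as escaping inactivation, a list of genes reported to stay active on the inactive X chromosome, started higher, at 13.8% ± 6.07. They stood at 36.8% ± 3.13 and 36.2% ± 5.30 in the RepB genotypes. The list was mixed in wild type, where 8 and 7 of its 14 genes lay over 10% in replicates 1 and 2, and 3 and 4 lay at 0. Pooled over genes, 10.1%, 36.7% and 38.1% of the X-linked allelic reads were from 129. Genes of chromosome 13, which carries both strains' alleles in these cells, were taken as background after the shares were seen. They had medians of 50.4% ± 0.537, 50.3% ± 0.488 and 50.0% ± 0. The X-linked difference from wild type was 27.4 percentage points in RepB+/- and 28.9 in RepB-/-, each with an exact permutation p of 0.333, the smallest two-sided value that 2 libraries against 2 allow. RepB-/- lay 1.43 points above RepB+/- (exact permutation p = 1).

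**Figure D1:**
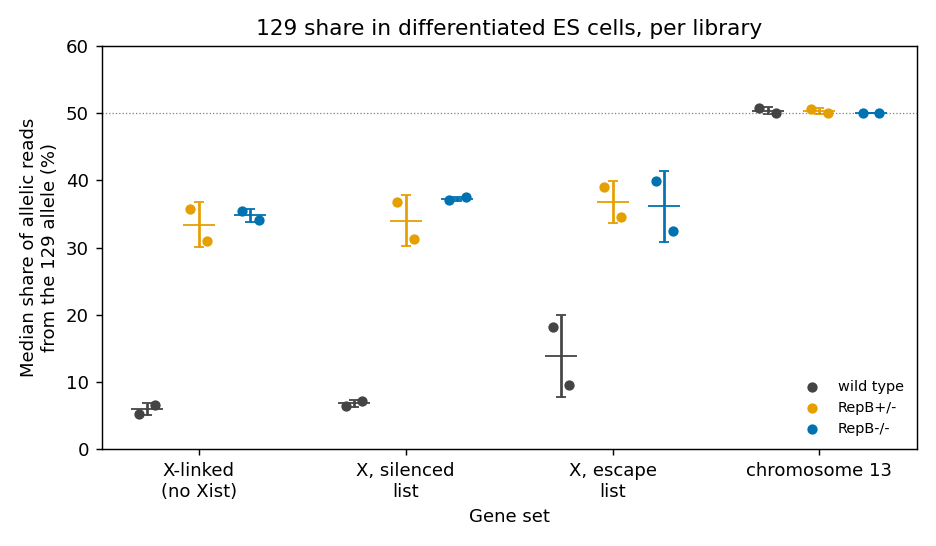
Median share of allelic reads from the 129 allele in percent (vertical axis) in each ES library (points), with the genotype mean and SD (n = 2, bars), for X-linked genes without Xist, the fixed lists of X-linked genes subject to inactivation and escaping it, and chromosome 13 genes. X-linked means are 5.94%, 33.4% and 34.8% in wild type, RepB+/- and RepB-/-, and chromosome 13 means lie between 50.0% and 50.4%.

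Gene by gene, the 129 share of most measured X-linked genes rose in both RepB genotypes. Flna, which encodes the actin crosslinker filamin A, went from 5.41% ± 0.222 (SD, n = 2) in wild type to 43.3% ± 3.03 in RepB+/- and 44.8% ± 0.641 in RepB-/-. Lamp2, a lysosomal membrane protein gene, went from 3.52% ± 1.41 to 41.5% ± 0.736 and 42.8% ± 0.529. Of 377 X-linked genes tested with edgeR for a change in the ratio of 129 to CAST reads, 225 shifted toward 129 and 1, Xist, toward CAST in RepB+/-, and 234 and 1 (Xist again) did so in RepB-/-. The median log2 change of the ratio was 2.86 in RepB+/- and 2.91 in RepB-/-, and for Flna it was 3.74 (SE 0.14, adjusted p = 1.4e-148) and 3.83 (SE 0.14, adjusted p = 5.97e-156). Both RepB libraries lay above both wild-type libraries for 312 genes (82.8%) in RepB+/- and for 339 (89.9%) in RepB-/-, where chance gives 16.7%. On the autosomes 52 and 47 of 11220 genes were called, of which 1 and 1 were among the 418 of chromosome 13. Most autosomes showed almost only 129 reads, so most of their genes had little room to shift. Chromosome 13, with both alleles, is the fairer background. DESeq2 called 146 X-linked genes in RepB+/- and 161 in RepB-/-.

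Among 39 measured genes of the list subject to X inactivation, 31 shifted toward 129 in RepB+/- and 32 in RepB-/-, or 35 and 35 adjusted over the list alone. Of 14 measured escape genes 8 shifted toward 129 in each genotype, or 9 and 9 adjusted over the list alone. Among those that shifted were Shroom4, Syap1 and Mid1, with only 0.725%, 4.18% and 3.42% of reads from 129 in wild type. The count is therefore not one of genes that all escaped inactivation in these wild-type cells. Kdm5c, a histone demethylase gene known to escape inactivation, went from 23.5% ± 1.52 (SD, n = 2) in wild type to 39.4% ± 4.66 and 42.0% ± 1.37, and the RNA helicase gene Ddx3x from 19.4% ± 1.17 to 39.1% ± 4.28 and 42.6% ± 0.651. The demethylase gene Kdm6a, with 32.3% ± 10.3, 44.7% ± 1.03 and 41.2% ± 2.94, was not called in either genotype. Of 4 measured genes of the X inactivation centre, the region around Xist, 1 shifted toward 129 in each genotype, or 3 adjusted over the list alone. Between RepB-/- and RepB+/- edgeR called 2 X-linked genes, Xist toward CAST and the ribosomal protein gene Rpl39 toward 129, and 6 had an unadjusted p under 0.05. Rpl39 shares sequence with copies elsewhere, so its 129 shares (96.8% ± 2.19, 94.1% ± 8.39 and 99.3% ± 0.691) are uncertain.

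Along the chromosome, the median share was raised in every stretch of 20 Mb (mm9; positions are those of the exon the table lists for each gene). In RepB+/- it ranged from 22.4% ± 1.95 (SD, n = 2) over 53 genes between 120 and 140 Mb to 41.5% ± 0.736 over 25 genes between 20 and 40 Mb. In RepB-/- the same stretches had 26.1% ± 0.25 and 42.3% ± 0.0980. The stretch from 100 to 120 Mb, which holds Xist, had 27.95% ± 6.69 and 29.7% ± 1.68 over 28 genes. Wild type lay between 3.84% and 9.09% in all of them.

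**Figure D2:**
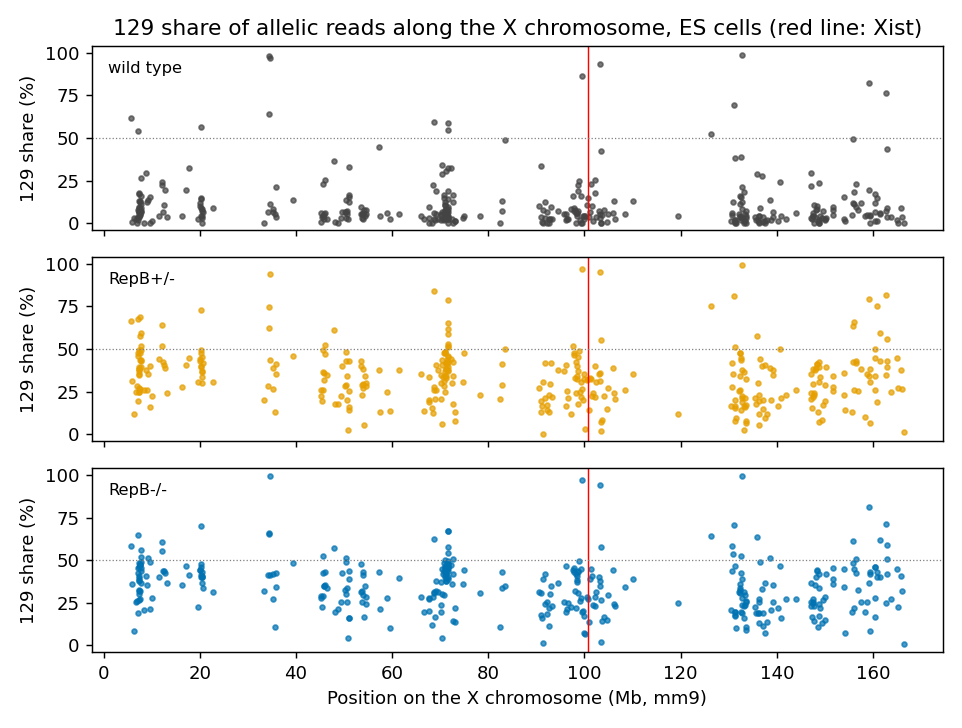
Share of 129 reads in percent (vertical axes, mean of 2 libraries per genotype) of each of 376 X-linked genes (points) by position on chromosome X in Mb (mm9), in wild type, RepB+/- and RepB-/- ES cells from top to bottom, with Xist as a red line. Most wild-type genes lie near the bottom, with 262 under 10%, and most RepB genes lie above them along the whole chromosome.

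Reads of the 2 alleles were then scaled by library size to see which chromosome changed. Over the 376 X-linked genes the median log2 change of 129 reads was 2.41 ± 0.293 (SD, n = 2) in RepB+/- and 2.53 ± 0.0638 in RepB-/-. That of CAST reads was -0.15 ± 0.113 and -0.14 ± 0.0231, and that of all reads of these genes was 0.31 ± 0.087 and 0.31 ± 0.024. On chromosome 13 the medians of 129, CAST and all reads lay between -0.02 and 0.07 in both genotypes.

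**Figure D3:**
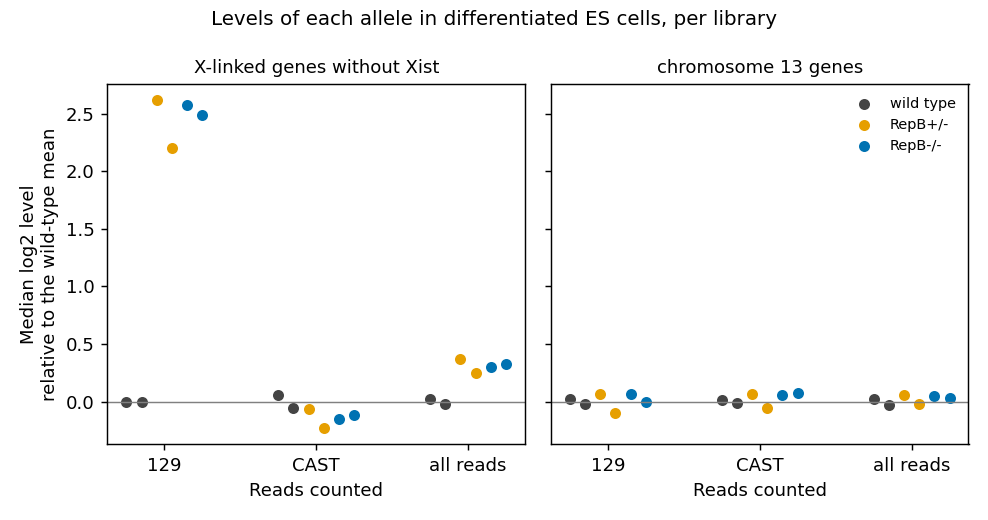
Median log2 level relative to the wild-type mean (vertical axis) of 129 reads, CAST reads and all reads in each ES library (points), for X-linked genes without Xist on the left and chromosome 13 genes on the right. X-linked 129 reads average 2.41 in RepB+/- and 2.53 in RepB-/-, and CAST reads -0.15 and -0.14.

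Counted over all reads, whichever allele they came from, RepB+/- cells had more transcripts of X-linked, stem cell and endoderm genes than wild-type cells. They had fewer transcripts of heart muscle genes. With the correlation between genes estimated from the data, the list test called none of these groups. The pluripotency factor genes Pou5f1 (log2 fold change 1.63, SE 0.16, edgeR adjusted p = 1.78e-05), Nanog (1.65, SE 0.16, adjusted p = 1.67e-05) and Sox2 (1.63, SE 0.14, adjusted p = 5.97e-06) rose, as did Afp (1.67, SE 0.12, adjusted p = 3.83e-06), which encodes a fetal serum protein of the yolk sac and liver. The heart myosin genes Myh7 (-1.40, SE 0.11, adjusted p = 3.83e-06) and Myh6 (-1.46, SE 0.15, adjusted p = 2.96e-05) fell. Among called genes with a mean of at least 5 CPM and no overlap between the libraries compared, the highest log2 fold changes were those of Trh (3.33), a thyrotropin-releasing hormone gene, Mfi2 (2.70), which encodes melanotransferrin, and the Nodal antagonist gene Lefty2 (2.53), and the lowest were those of the imprinted gene Phlda2 (-1.84), the ventricular transcription factor gene Irx4 (-1.78) and the X-linked receptor gene Gpr50 (-1.69).

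Of 562 X-linked genes tested in RepB+/-, 188 rose and 25 fell, or 226 and 33 adjusted over the list alone. Their median log2 fold change was 0.37 (1.30-fold), 451 (80.2%) were positive, and the median of 14587 autosomal genes was 0.01. Pdzd4 (1.56), the angiogenic growth factor gene Figf (1.70) and the synaptic vesicle gene Syn1 (1.70) rose, and Gpr50, Esx1 (-1.50), a placental homeobox gene, and Ldoc1 (-1.03) fell. The set test gave an adjusted p of 4.87e-13 for X-linked genes with the preset correlation and an adjusted p = 0.303 with an estimated correlation. The counts of 188 and 25 became 106 and 10 without wild-type replicate 1 and 78 and 12 without wild-type replicate 2, and 103 rose without RepB+/- replicate 1.

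Among lists fixed in advance, 16 of 18 pluripotency genes rose and 1 fell (16 and 2 adjusted over the list alone; median log2 fold change 1.63). Of 22 endoderm and yolk sac genes 15 rose (16 adjusted over the list alone; median 0.76), among them Trf (1.77), the transferrin gene, and the apolipoprotein gene Apob (1.60). Of 23 cardiac muscle genes 14 fell (16 adjusted over the list alone; median -0.73), among them the heart transcription factor gene Hand1 (-1.09) and the cardiac actin gene Actc1 (-0.87). The set test called these lists with adjusted p values of 1.71e-30, 8.08e-15 and 7.55e-14, and each had adjusted p = 0.146 with an estimated correlation. Of 42 genes subject to X inactivation 23 rose (27 adjusted over the list alone; median 0.40), among them the cohesin gene Smc1a (0.59), G6pdx (0.87), which encodes an enzyme of the pentose phosphate pathway, and Xiap (0.59), an inhibitor of apoptosis. The set test gave adjusted p = 6.12e-10 for that list, or adjusted p = 0.248 with an estimated correlation. Of 16 escape genes 5 rose and 1 fell, over all genes and adjusted over the list alone (median 0.11, set test adjusted p = 0.0233, adjusted p = 0.408 with an estimated correlation), with Utp14a (0.88) and Syap1 (0.75) among those that rose. Without wild-type replicate 1, wild-type replicate 2 or RepB+/- replicate 1, the genes that rose were 7, 9 and 8 of the endoderm list and 9, 6 and 11 of those subject to X inactivation. The escape gene that fell lost its call without either wild-type library or RepB+/- replicate 2, and the pluripotency gene that fell without wild-type replicate 2.

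Further lists moved in part. Of 33 Hox genes 6 rose (8 adjusted over the list alone; median 0.58, set test adjusted p = 0.00143), led by Hoxb9 (1.70), and the list had adjusted p = 0.450 with an estimated correlation. Of 13 immediate early and stress genes 1 rose, Egr1 (0.70), and 7 fell, among them Ddit3 (-1.05), a gene of the unfolded protein response, and the heat shock gene Hspa1b (-1.17), with the same counts adjusted over the list alone (median -0.45, set test adjusted p = 0.000435, adjusted p = 0.303 with an estimated correlation). Of 10 epithelial genes 3 fell (4 adjusted over the list alone; median -0.29, adjusted p = 0.00536, adjusted p = 0.450 with an estimated correlation), among them the keratin gene Krt8 (-0.70). Of 19 proliferation genes 4 rose, as they did adjusted over the list alone (median 0.23, adjusted p = 0.0160, adjusted p = 0.441 with an estimated correlation), among them Bub1 (0.62) of the spindle checkpoint and the replication helicase gene Mcm6 (0.59). Of 10 blood genes 4 rose, as they did adjusted over the list alone (median 0.53, adjusted p = 0.0160, adjusted p = 0.408 with an estimated correlation), among them Spi1 (1.09), a myeloid transcription factor gene, whose call was lost without wild-type replicate 2 (adjusted p = 0.102) and without RepB+/- replicate 2 (adjusted p = 0.0508). Single libraries moved these counts. The 6 Hox genes became 3 and 1 without wild-type replicates 1 and 2, 10 and 2 without RepB+/- replicates 1 and 2, and 3 without either RepB-/- library. The 7 stress genes that fell became 3 without wild-type replicate 2 and 4 without RepB+/- replicate 1, and the 3 epithelial genes became 1 without wild-type replicate 2. Without either wild-type library or RepB+/- replicate 1, 2 proliferation genes rose. The 4 blood genes became 1 without wild-type replicate 1, 0 without wild-type replicate 2 and 0 without RepB+/- replicate 2.

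The set test did not call the remaining lists in RepB+/-. Of 11 subunit genes of Polycomb repressive complex 2 (PRC2), 2 rose and 0 fell, over all genes and adjusted over the list alone (median -0.04, mean 0.04, adjusted p = 0.806). They were Suz12 (0.43) and Mtf2 (0.53), and both calls were lost without wild-type replicate 2 (adjusted p = 0.249 and 0.107) and without RepB+/- replicate 1 (adjusted p = 0.0753 and 0.141). Of 20 PRC1 subunit genes 1 rose and 1 fell (2 and 5 adjusted over the list alone; median -0.15, adjusted p = 0.335). Of 9 genes of the X inactivation centre 3 rose, as they did adjusted over the list alone (median 0.20, adjusted p = 0.147), among them Tsix (1.57), whose call was lost without wild-type replicate 1 (adjusted p = 0.0640). Neural genes split, with 4 of 15 up and 4 down over all genes and adjusted over the list alone (median -0.27 and set test direction up, adjusted p = 0.767), and Nes (1.02), Otx2 (1.60) and Stmn2 (1.06) rose. The counts over all genes and adjusted over the list alone were also equal for the next lists. Of 19 fibroblast genes 4 rose and 1 fell (median -0.02, mean 0.09, adjusted p = 0.806), and of 27 imprinted genes 4 rose and 4 fell (median 0.01, mean -0.03, adjusted p = 0.335), with Grb10 (1.35) up and Cdkn1c (-0.88) down. Of 10 endothelial genes 3 rose and 2 fell (4 and 4 adjusted over the list alone; median 0.23, adjusted p = 0.744). Of 13 p53 target genes edgeR called 0 (1 up and 2 down adjusted over the list alone; median -0.19, adjusted p = 0.328), 3 had an unadjusted p under 0.05, and DESeq2 called 0. Without wild-type replicate 1, wild-type replicate 2 or RepB+/- replicate 1, 0, 1 and 1 genes of the X inactivation centre rose and 0, 2 and 1 neural genes fell. Both PRC1 calls were lost without either wild-type library. Without wild-type replicate 1 or RepB+/- replicate 1, 2 fibroblast genes rose, and 7 fell without RepB+/- replicate 2. The 4 imprinted genes that rose became 1 without either wild-type library and 2 without RepB+/- replicate 2, and the 2 endothelial genes that fell became 1 without wild-type replicate 2. Among p53 targets 1 fell without RepB+/- replicate 1, and 1 rose and 1 fell without RepB+/- replicate 2, and 1 PRC2 gene also fell without the latter. The 7 Y-linked genes had 0 counts over all 8 libraries, and the 22 mitochondrially encoded genes were not among the genes counted, so neither list was tested.

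Over all 15149 genes tested in RepB+/-, edgeR called 2418, of which 1382 rose and 1036 fell, and 529 rose and 120 fell by over 2-fold. The count was 1168 without wild-type replicate 1, 790 without wild-type replicate 2 and 1583 without RepB+/- replicate 1.

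**Figure D4:**
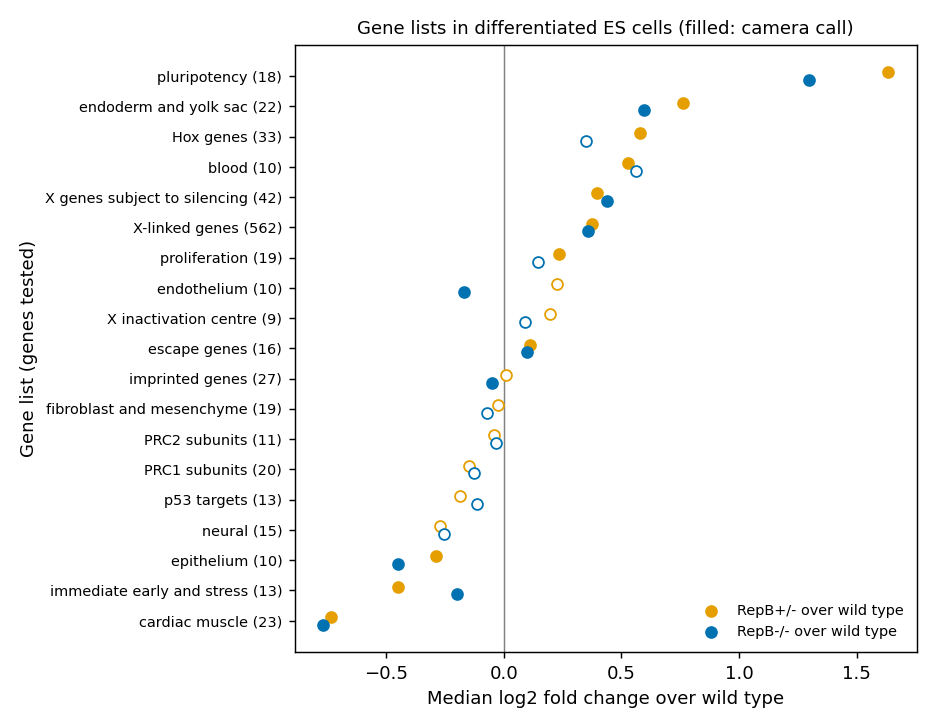
Median log2 fold change over wild type (horizontal axis) of X-linked genes and of each fixed gene list, with the number of genes tested in brackets, in RepB+/- and RepB-/- ES cells, where filled points were called by the set test with the preset correlation. Pluripotency genes lie highest (1.63 and 1.30) and cardiac muscle genes lowest (-0.73 and -0.77).

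Against wild type, RepB-/- cells also had more pluripotency, endoderm and X-linked transcripts and fewer of heart muscle. Here too the list test called none of these groups with an estimated correlation, and only 7 of 22 endoderm genes were called. Pou5f1 (log2 fold change 1.35, SE 0.15, edgeR adjusted p = 5.61e-05) and Nanog (1.36, SE 0.15, adjusted p = 5.55e-05) rose, as did Afp (1.40, SE 0.12, adjusted p = 8.51e-06), and Myh7 (-2.21, SE 0.11, adjusted p = 3.13e-08) and Myh6 (-2.09, SE 0.16, adjusted p = 1.75e-06) fell. Under the same limits, the highest log2 fold changes that held with every library left out in turn were those of Ptprq (2.44), a receptor phosphatase gene, Lefty1 (2.31), the collagen gene Col6a6 (2.30) and the potassium channel subunit gene Kcnab1 (2.19). The lowest were those of Mfi2 (-2.55), Myh7, Myh6, Irx4 (-1.94) and Phlda2 (-1.84). Rpl36a (2.43), an X-linked ribosomal protein gene with copies elsewhere, lost its call without either wild-type library or RepB-/- replicate 1 (adjusted p = 0.121, 0.209 and 0.616) and is uncertain.

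Of 562 X-linked genes tested in RepB-/-, 177 rose and 29 fell, or 232 and 39 adjusted over the list alone. Their median log2 fold change was 0.36 (1.28-fold), 432 (76.9%) were positive, and the autosomal median was 0.00. Figf (1.80), Pdzd4 (1.20) and Atp6ap2 (0.92), which encodes a partner of the vacuolar proton pump, rose, and Esx1 (-1.77), Gpr50 (-1.66) and Dmrtc1b (-1.61) fell. The set test gave an adjusted p of 1.40e-12, or adjusted p = 0.259 with an estimated correlation. The counts of 177 and 29 became 103 and 10 without wild-type replicate 1, 84 and 9 without wild-type replicate 2, 111 and 17 without RepB-/- replicate 1, and 111 and 11 without RepB-/- replicate 2.

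Of the fixed lists, 14 of 18 pluripotency genes rose and 1 fell in RepB-/- (15 and 1 adjusted over the list alone; median 1.30), 7 of 22 endoderm genes rose (11 adjusted over the list alone; median 0.59), and 15 of 23 cardiac genes fell over all genes and adjusted over the list alone (median -0.77), among them Actc1 (-1.21) and the sarcomere gene Actn2 (-1.48). Their set test adjusted p values were 8.53e-19, 1.21e-08 and 1.29e-22, or adjusted p = 0.182, 0.182 and 0.0599 with an estimated correlation. Of 42 genes subject to X inactivation 18 rose (29 adjusted over the list alone; median 0.44, adjusted p = 4.11e-13, adjusted p = 0.182 with an estimated correlation), among them G6pdx (1.04), the polyamine enzyme gene Sat1 (0.82) and Timp1 (0.65), a metalloproteinase inhibitor gene. Of 16 escape genes 5 rose and 1 fell over all genes and adjusted over the list alone (median 0.10, adjusted p = 0.0332, adjusted p = 0.386 with an estimated correlation), with Syap1 (0.71) among those up. Of 10 endothelial genes 3 fell (1 up and 4 down adjusted over the list alone; median -0.17, adjusted p = 0.0457, adjusted p = 0.430 with an estimated correlation), namely the vascular endothelial growth factor receptor genes Kdr (-1.02) and Flt1 (-0.65) and the junction cadherin gene Cdh5 (-0.71). Of 10 epithelial genes 4 fell (1 up and 5 down adjusted over the list alone; median -0.45, adjusted p = 0.000478, adjusted p = 0.430 with an estimated correlation), among them Krt8 (-0.72), whose call was lost without RepB-/- replicate 2 (adjusted p = 0.0572). Of 27 imprinted genes 1 rose, Grb10 (0.95), and 4 fell, among them Phlda2 and Cdkn1c (-0.69), over all genes and adjusted over the list alone (median -0.05, adjusted p = 0.0370, adjusted p = 0.484 with an estimated correlation). Of 13 immediate early and stress genes 1 rose and 4 fell (1 and 5 adjusted over the list alone; median -0.20, adjusted p = 0.0108, adjusted p = 0.386 with an estimated correlation). Here too, single libraries moved the counts. Without wild-type replicate 2, 8 cardiac genes fell. The 18 genes subject to X inactivation became 10 and 7 without wild-type replicates 1 and 2 and 11 without RepB-/- replicate 2. The 5 escape genes became 2 without wild-type replicate 1 and 3 without either RepB-/- library, and the 1 that fell lost its call without any single library of either genotype. Endoderm genes went the other way, with 12 up without either RepB+/- library. The 4 epithelial genes became 1 without wild-type replicate 2 and 0 without RepB-/- replicate 2, and the 4 imprinted genes that fell became 2 without wild-type replicate 2 or either RepB-/- library. The 4 stress genes that fell became 2 without wild-type replicate 1 or RepB-/- replicate 1, and 0 without wild-type replicate 2 or RepB-/- replicate 2.

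The set test did not call the other lists in RepB-/-. Of 33 Hox genes 5 rose over all genes and adjusted over the list alone (median 0.35, adjusted p = 0.0503, and 0.0432 with DESeq2 size factors), of 10 blood genes 5 rose (6 adjusted over the list alone; median 0.56, adjusted p = 0.0736), and of 19 proliferation genes 3 rose over all genes and adjusted over the list alone (median 0.15, adjusted p = 0.0993). Neural genes again split, with 3 of 15 up and 4 down over all genes and adjusted over the list alone (median -0.25, adjusted p = 0.619), Nes (0.74) and Stmn2 (0.89) among those up. Of 19 fibroblast genes 5 rose and 2 fell over all genes and adjusted over the list alone (median -0.07, mean 0.07, adjusted p = 0.760), with Dcn (0.97), the decorin gene, up and the matrix gene Postn (-0.84) down. Of 13 p53 targets 1 rose and 1 fell over all genes and adjusted over the list alone (median -0.11, adjusted p = 0.659), and of 20 PRC1 genes 1 fell (0 adjusted over the list alone; median -0.13, adjusted p = 0.222). EdgeR called 0 of 11 PRC2 genes (3 up and 3 down adjusted over the list alone; median -0.03, adjusted p = 0.789), 6 had an unadjusted p under 0.05 and DESeq2 called 0. It called 0 of 9 X inactivation centre genes, also adjusted over the list alone (median 0.09, adjusted p = 0.521), 1 had an unadjusted p under 0.05 and DESeq2 called 0. That gene was Tsix (1.02, SE 0.33, adjusted p = 0.0522). With 1 library left out, the 5 Hox genes became 3 and 1 (wild-type replicates 1 and 2) and 3 and 0 (RepB-/- replicates 1 and 2). The 5 blood genes became 2 and 1 without wild-type replicates 1 and 2 and 0 without RepB-/- replicate 2. Proliferation genes had 0 calls without either wild-type library or RepB-/- replicate 1, and 1 without RepB-/- replicate 2. The 4 neural genes that fell became 1 without wild-type replicate 1 or RepB-/- replicate 1 and 0 without RepB-/- replicate 2, and the 5 fibroblast genes that rose became 3 without wild-type replicate 2 or either RepB-/- library. Both p53 target calls were lost without wild-type replicate 2, and the PRC1 call was lost without either wild-type or either RepB-/- library. Without either RepB+/- library there were gains: 1 PRC2 gene rose and 1 fell, 1 gene of the X inactivation centre, Tsix, rose, and 1 PRC1 gene rose and 2 fell.

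Over all genes, edgeR called 1933 in RepB-/- against wild type, of which 1101 rose and 832 fell, and 415 rose and 139 fell by over 2-fold. The count was 990 without wild-type replicate 1, 687 without wild-type replicate 2, 992 without RepB-/- replicate 1 and 837 without RepB-/- replicate 2.

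The calls of both genotypes overlapped: 813 genes rose in both, 610 fell in both and 1 moved in opposite directions. Independent lists of these sizes would share 100.4 and 56.9 genes. Unchanged groups, simulated against shared wild-type libraries that were simulated too, had 0.1 and 0.05 genes in common on average over 20 simulations. Almost no gene is called in unchanged groups, so that overlap was bound to be near 0. It does not measure how much shared controls add to an overlap of long lists. Across genes, which are not independent replicates, the log2 fold changes correlated at 0.861 (simulated 0.528). Their covariance was 0.249 (simulated 0.0320), a difference of 0.217. A split of the 2 wild-type libraries would leave 1 for each genotype and was not made, so part of the excess over independent lists may come from the shared controls.

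Set directly against each other, RepB-/- and RepB+/- cells differed in few genes. The largest difference was in Mfi2, at 6.40 CPM in wild type, 41.8 in RepB+/- and 1.11 in RepB-/- (log2 fold change -5.25, SE 0.26, edgeR adjusted p = 2.10e-08). Its neighbours on chromosome 16, Ncbp2 (-0.66), of the cap-binding complex, and the kinase gene Pak2 (-0.63), also fell, as did Myh7 (-0.81), Trh (-1.27), Lin28a (-0.77), which encodes an RNA-binding protein of stem cells, and 3 genes of blood vessels, Dll4 (-1.33), Sox18 (-0.96) and Plvap (-0.81). Car9 (0.89), a carbonic anhydrase gene, Pappa2 (0.88) and Gpnmb (0.73) rose. EdgeR called 13 genes in all, 3 up and 10 down, 1003 had an unadjusted p under 0.05, and DESeq2 called 30. More genes were also called with no filter and with the replicate number as a block, as given in the part on processing. The count was 6 without wild-type replicate 1, 8 without wild-type replicate 2, 66 and 34 without RepB+/- replicates 1 and 2, and 4 and 3 without RepB-/- replicates 1 and 2, and each of the 13 genes but Mfi2 lost its call in at least 1 of these.

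Between the RepB genotypes edgeR detected no X-linked difference in counts of all reads at this depth. It called 0 of 562 X-linked genes, also adjusted over the list alone (median -0.03, set test adjusted p = 0.322), 43 had an unadjusted p under 0.05 and DESeq2 called 1. Without RepB+/- replicates 1 and 2 edgeR called 1 and 5, all lower in RepB-/-. Pluripotency genes were lower in RepB-/- as a list (median -0.32, set test adjusted p = 2.89e-09, adjusted p = 0.422 with an estimated correlation), with 1 of 18 called down, or 7 adjusted over the list alone. So were cardiac genes (median -0.13, adjusted p = 0.00161, adjusted p = 0.323 with an estimated correlation), with 1 of 23 called down, or 3 adjusted over the list alone. The pluripotency call was lost without either wild-type library, RepB+/- replicate 1 or RepB-/- replicate 2, and the cardiac call without either RepB-/- library. Endothelial genes (median -0.38, adjusted p = 1.92e-06, 5 of 10 down adjusted over the list alone), endoderm genes (median -0.24, adjusted p = 5.99e-06, 0 of 22 adjusted over the list alone) and Hox genes (median -0.24, adjusted p = 0.0109, 0 of 33 adjusted over the list alone) were lower as lists, with adjusted p = 0.323, 0.335 and 0.576 with an estimated correlation. EdgeR called 0 single members of these 3 lists, 5, 7 and 3 had an unadjusted p under 0.05 and DESeq2 called 0, 0 and 0. The remaining lists were not called as lists and edgeR called 0 of their members over all genes. Adjusted over the list alone, 2 genes of the X inactivation centre fell, as did 1 neural and 1 imprinted gene, while 3 stress genes, 1 gene subject to X inactivation and 1 fibroblast gene rose, and 0 of the other lists passed. At an unadjusted p under 0.05 these were 1 of 16 escape genes, 2 of 42 genes subject to X inactivation, 2 of 9 X inactivation centre genes, 0 of 11 PRC2 genes, 2 of 20 PRC1 genes, 3 of 15 neural genes and 1 of 19 fibroblast genes, 3 of 10 blood genes, 1 of 10 epithelial genes, 5 of 27 imprinted genes, 1 of 19 proliferation genes, 0 of 13 p53 targets and 5 of 13 stress genes, and DESeq2 called 1 fibroblast gene among them and 0 of the others. Some lists with 0 calls gained some with a library left out: without RepB+/- replicate 2, 1 endoderm, 1 neural and 1 imprinted gene fell, and without RepB+/- replicate 1, 1 imprinted gene fell and 1 stress gene rose and 1 fell.

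In MEF, with 1 library per genotype and so no replicate check, X-linked genes as a whole moved little between RepB and wild type. Xist stood at 427 CPM in wild type and 499 in RepB (ratio 1.17, 95% interval 1.13 to 1.21). The median log2 ratio of RepB to wild type over 368 X-linked genes was -0.05 (-0.08 to -0.00), at percentile 0.3 of 10000 random autosomal lists of matched expression, and 0.10 with scaling by total counts, which raised the median of all genes by 0.15. The random lists mix all autosomes, while medians of single autosomes ran from -0.23 (chromosome 4) to 0.38 (chromosome 15). That percentile therefore does not set the X chromosome apart from other chromosomes. Genes subject to X inactivation had a median of -0.07 (41 genes, percentile 27.7), or 0.08 with scaling by total counts, and escape genes one of 0.28 (16 genes, percentile 97.1). Of 11672 genes, 367 were over 2-fold higher and 760 over 2-fold lower in RepB. Among the highest ratios were those of Foxq1 (7.18, 4.55 to 12.0), a forkhead factor gene, Eda2r (6.74), a receptor gene of the tumour necrosis factor family, and the peptidase gene Mme (5.28). The basement membrane gene Nid1 had 6464 counts in wild type and 8 in RepB, Mfap2, of the elastic fibre, 913 and 1, and Khdrbs3 290 and 0, which is at least 165-fold lower against a floor of 3 counts.

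Among the fixed lists in MEF, p53 target genes stood highest (median log2 ratio 0.97 over 12 genes, percentile 100), with the cell cycle inhibitor gene Cdkn1a at a ratio of 2.94 (2.72 to 3.17) and Mdm2, which encodes the ubiquitin ligase of p53, at 2.09 (1.91 to 2.29). Immediate early and stress genes were low (median -1.08 over 13 genes, percentile 0), Egr1 having a ratio of 0.109 (0.1 to 0.118). Imprinted genes were low too (median -0.75 over 22 genes, percentile 0), with H19 at 349 CPM in wild type and 13.8 in RepB, and Meg3 at 189 and 6.07. Fibroblast genes had a median of -0.39 (18 genes, percentile 1.15), with fibronectin, Fn1, at a ratio of 0.459. The other medians were 0.42 for the X inactivation centre (6 genes, percentile 94.3), 0.28 for Hox genes (17 genes, percentile 94.0), 0.08 for proliferation genes (19 genes, percentile 97.3), 0.47 for endoderm genes (5 genes, percentile 91.5), -0.97 for neural genes (6 genes, percentile 0.21) and -1.41 for pluripotency genes (3 genes, percentile 0.21). PRC2 and PRC1 genes had medians of 0.03 (11 genes, percentile 52.0) and 0.01 (20 genes, percentile 54.6). Under 3 genes of the cardiac, endothelial, blood and epithelial lists were expressed, so these lists have no value.

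X-linked reads in both MEF libraries came almost wholly from the CAST chromosome. The median 129 share over 240 X-linked genes without Xist was 0% in wild type, with 124 genes at 0, and 0.425% in RepB, with 107 at 0. Pooled over genes it was 3.61% (95% exact interval 3.46 to 3.76) in wild type and 4.90% (4.75 to 5.05) in RepB. Over 11 escape genes the median was 20.6% in wild type and 25.5% in RepB, and over 33 genes subject to X inactivation it was 0.392% and 0.718%. The exact intervals of the 2 libraries lay apart for 5 genes. Timp1, with 0 of 166 allelic reads from 129 in wild type and 8.96% (5.88 to 12.9) of 279 in RepB, and Sh3kbp1, with 1.33% and 20.5%, were higher in RepB, and Plp2 (60.5% and 52.0%), Apex2 (19.8% and 2.87%) and Rbbp7 (80.6% and 67.6%) were lower. Xist reads were 99.7% and 99.2% from 129.

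Several MEF autosomes differed in allelic share between the libraries. The median 129 share of chromosome 4 was 56.9% in wild type and 34.2% in RepB, that of chromosome 7 46.1% and 65.4%, of chromosome 10 50.9% and 65.9%, of chromosome 15 52.4% and 66.0%, of chromosome 3 50.8% and 60.5%, and of chromosome 1 41.1% and 49.1%. Over all autosomal genes it was 49.3% and 51.0%. Total reads moved on the same chromosomes, with median log2 ratios of RepB to wild type of 0.38 on chromosome 15, 0.37 on chromosome 3, 0.31 on chromosome 10, -0.23 on chromosome 4, -0.17 on chromosome 1 and -0.15 on chromosome 7. On chromosome 4 the median log2 ratio was -0.94 for 129 reads and 0.36 for CAST reads, and on chromosome 10 it was 0.68 and -0.17. These values compare 2 libraries, not the genotypes.

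**Figure D5:**
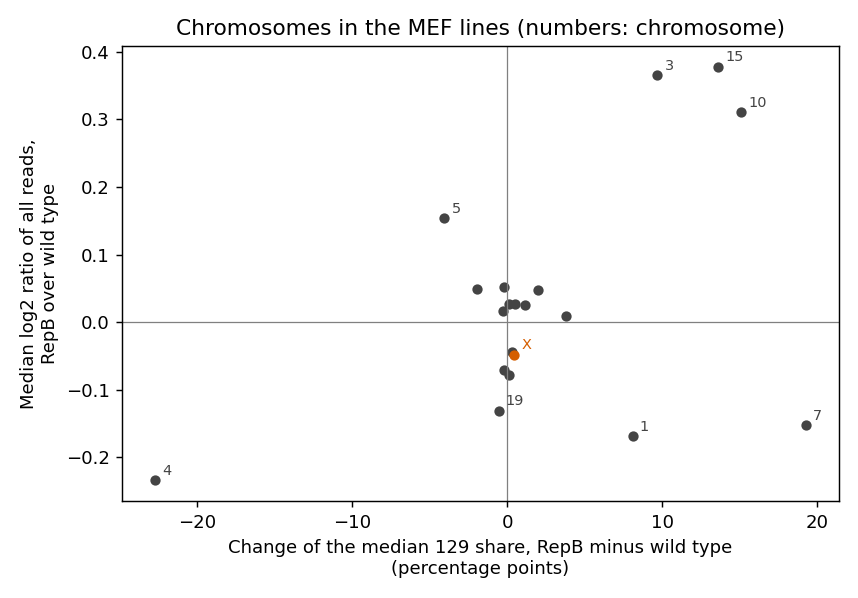
Change of the median 129 share in percentage points (horizontal axis) against the median log2 ratio of all reads (vertical axis), RepB over wild type, for each chromosome (points) in the 2 MEF libraries. Chromosome 4 lies at -22.7 points and chromosome 7 at 19.3, and the X chromosome lies near the origin.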

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

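No test in this part was chosen after the result was seen, since the differences between ES cells and MEF below were not tested. With 1 MEF library per genotype, the lists fixed in advance were compared only by direction: every RepB ES library lay on one side of wild type and the MEF library on the other.

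X-linked genes had a median log2 ratio of -0.0483 (95% interval -0.08 to -0.00) in RepB MEF over 368 genes, and medians of 0.30 to 0.44 over 562 genes in the RepB ES libraries. Single MEF autosomes had medians from -0.23 (chromosome 4) to 0.38 (chromosome 15), a range that holds the X-linked MEF median. For genes subject to X inactivation the MEF median was -0.0697 (95% interval -0.39 to 0.15, percentile 27.7 of random lists) over 41 genes, an interval that spans 0, and the ES medians 0.29 to 0.45 over 42. Scaling by total counts, which raised the median of all MEF genes by 0.15, gave 0.10 and 0.08, and both medians lay below that of all genes with either scaling (0.01 with TMM and 0.16 with total counts). Pluripotency genes had a MEF median of -1.41 and ES medians of 1.19 to 1.80, but only 3 of the 18 genes tested in ES cells were expressed in MEF, namely Klf2 (ratio 0.346), Tbx3 (0.371) and Klf4 (1.30).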

How the results depend on the processing

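The correction of ES shares by chromosome 13 odds and the MEF scaling by autosomes with a steady allelic share are the tests in this part that were chosen only after the result was seen. No result reversed its direction once called. The median of X-linked genes kept its direction and call with every library left out (0.29 to 0.43 in RepB+/- and 0.33 to 0.36 in RepB-/-, highest adjusted p = 6.42e-07), with other scalings and filters and with the replicate block. With an estimated correlation the medians of 0.37 and 0.36 were no longer called (adjusted p = 0.303 and 0.259). Of the fixed lists, 0 were called in RepB+/- against wild type, 0 in RepB-/- against wild type and 0 between the RepB genotypes. The size of the correlation alone does not account for this. For cardiac genes between the RepB genotypes it was estimated at 0.0062, below the preset 0.01. Their unadjusted camera p still went from 0.000339 to 0.0340. What else differs between the settings was not tested. Depth and 2 libraries per genotype limit small changes: the simulations recovered 56.7%, 53.7% and 50.8% of 1.5-fold changes.

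Between RepB-/- and RepB+/- the 13 calls became 124 with no filter (50 up, 74 down, all 13 kept), 30 with DESeq2 (13 up, 17 down, 12 of the 13 kept) and 6 with only the 4 libraries compared (1 up, 5 down), a fit with fewer samples. For the first 2 of these the cause was not tested. With at least 5 CPM, where fewer genes are tested, 19 X-linked genes fell in RepB-/- against wild type, where 29 fell with the main filter. DESeq2 called 146 X-linked allelic shifts in RepB+/-, 146 of them toward 129, and the cause was not tested. Over genes with at least 100 allelic reads, a smaller set, the 129 share in RepB-/- exceeded wild type by 30.8 points. Division by the autosomal median on the odds scale gave 0.562 and 0.599 points, but is void because most autosomes show 129 reads almost alone, and with chromosome 13 in its place the differences were 27.2 and 28.95. In MEF, scaling by total counts gave X-linked genes a median of 0.10, through the shift of all genes, and scaling by steady autosomes -0.05. Pooling MEF reads, which weights genes by their reads, gave a share difference of 1.295 points.

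With each library left out, a fit with fewer samples in which the lone library of a genotype is assumed to vary like the others, RepB+/- had 790 to 2620 calls (519 to 1500 up, 271 to 1120 down), with 78 to 207 X-linked genes up and 10 to 24 down. RepB-/- had 687 to 2760 calls (440 to 1541 up, 247 to 1219 down), with 84 to 221 X-linked genes up and 9 to 38 down. The lowest totals, 790 and 687, were those without wild-type replicate 2. The genotypes differed in 3 (without RepB-/- replicate 2) to 66 genes (without RepB+/- replicate 1), with 1 to 16 up and 1 to 50 down. In RepB+/- 0 to 1 X-linked genes shifted toward CAST, with 0 without wild-type replicate 1. Of named genes' results with a library left out, 1141 kept their side of the threshold, 174 lost a call and 11 gained one, and for allelic shifts these were 653, 37 and 2. Under other settings the figures were 838, 26 and 18 for genes, 297 and 23 (kept and lost) for allelic shifts, and 83, 24 and 1 for lists, the gain being Hox genes in RepB-/- with DESeq2 size factors (adjusted p = 0.0432). Of share results 18 stayed within the replicate spread with a library left out, and under other settings 17 stayed and 9 moved.

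The replicate numbers were also used as a block. Deviations of same-numbered libraries correlated at 0.107 between wild type and RepB+/-, 0.0696 between wild type and RepB-/- and 0.186 between the RepB genotypes. The labels name no shared batch, so the main fit took the libraries to share only a number. Same-numbered libraries were deposited together, however, and replicate 2 had fewer total counts than replicate 1 in each genotype. A shared batch is therefore not excluded. With the block, 1675 genes fell in RepB+/-, 3160 were called in RepB-/- (1667 up, 1493 down), and 80 between the genotypes (31 up, 49 down, all 13 kept), and the cause was not tested. Of named genes 210 kept their side of the threshold and 11 gained a call, 116 allelic shifts kept theirs, and 52 lists kept theirs while 2 gained a call, blood genes in RepB-/- (adjusted p = 0.0320) and imprinted genes between the genotypes (adjusted p = 0.0450).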

Other observations

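All tests of explanations in this part were chosen only after the result was seen.

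A few X-linked genes kept under 10% of their reads from 129 in RepB ES cells. Of 376 genes, 262 had under 10% of reads from 129 in wild type, and 185 of these had over 20% in both RepB genotypes. Another 113 were over 10% in all 3 genotypes. The 9 genes under 10% in both RepB genotypes were Cxx1c, Xlr3b, Eif2s3x, 1700011M02Rik, Pgk1, Tmsb15b2, Col4a6, S100g and G530011O06Rik, named here after their values were seen, of which Cxx1c and Xlr3b belong to families of near-identical copies and are uncertain. Low depth also makes Xlr3b, Tmsb15b2, Eif2s3x, G530011O06Rik and 1700011M02Rik uncertain. They averaged 22.8 to 37.5 allelic reads per library, near the minimum of 20. Col4a6, a basement membrane collagen gene with 1269 allelic reads per library, went from 1.59% ± 0.197 (SD, n = 2) to 9.43% ± 0.58 and 7.38% ± 1.24 in RepB+/- and RepB-/-, a called shift in each, and Pgk1, a glycolysis gene with 239, had 2.04% ± 2.88 and 2.18% ± 0.706. Across genes, which are not independent replicates, the 129 shares of both RepB genotypes had a Spearman correlation of 0.873.

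In MEF, several imprinted genes that are normally expressed from the paternal chromosome were far lower in the RepB library, with Peg3 at 126 CPM in wild type and 4.13 in RepB and Ndn at 92.3 and 1.17, as was the maternally expressed RNA gene Rian (61.1 and 1.53), while Mest had a ratio of 1.34 (95% interval 1.28 to 1.40). Hoxa9 was higher in RepB (ratio 9.67, 4.77 to 22.9). Thy1, a surface protein gene of fibroblasts, had 117 counts in wild type and 0 in RepB, at least 66.6-fold lower against a floor of 3 counts. In ES cells, chromosome 6 genes had a median log2 fold change of 0.13 in each RepB genotype over 773 genes, the highest of the autosomes in both. Prdx1, on chromosome 4, went from 19.7% of reads from 129 in wild type to 49.9% and 50.9% in the RepB genotypes. The median 129 share of chromosome 4 lay between 99.5% and 100% in every ES library, so the allele calls of Prdx1 are uncertain.

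X-linked 129 reads were more common in both RepB genotypes, and 3 technical or cellular explanations were set against the deletion. Undifferentiated cells with 2 active X chromosomes and little Xist could raise the share, as the rise of pluripotency genes would allow. As the whole cause, 46.7% and 50.3% of cells would be needed and Xist would fall to a log2 change of -0.91 and -1.01. Xist stood at -0.0703 (95% interval -0.41 to 0.27) in RepB+/- and 0.13 (-0.22 to 0.47) in RepB-/-. That argues against such cells as the whole cause, unless the other cells made more Xist. Both intervals reach below 0, so a smaller share of undifferentiated cells stays open. Xist and Tsix reads cannot be told apart here, which also limits this test. Allele calling or mapping that moved the X-linked odds would have moved chromosome 13 by 38.6 and 39.2 points, and it moved by -0.04 and -0.38. Cells silencing the CAST chromosome in place of the 129 one would bring CAST reads to -0.50 and -0.53 with all reads at 0, but CAST reads changed by -0.15 ± 0.113 (SD, n = 2) and -0.14 ± 0.0231 and all reads by 0.31 and 0.31, which argues against it as the whole cause, and 2.19% and 2.75% of Xist reads came from CAST in the RepB+/- libraries. In RepB-/- 10.8% and 12.8% did, so that a smaller share of such cells stays open there. An effect of the deletion on silencing of the 129 chromosome may account for the pattern, as a hypothesis that was not tested here. For RepB+/- this hypothesis assumes that the 129 copy of Xist lost the repeat, which the sample titles do not state. Differences between cell lines, which these libraries do not separate from genotype and independent clones would, stay open.

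A stretch of chromosome 16 from 31878896 to 32278501 (mm9), with 12 tested genes from Mfi2 to Rnf168, moved together in RepB+/- ES cells. Its median log2 fold change was 0.45 against wild type, where 3 copies in place of 2 would give 0.58, with 11 of 12 genes higher, and -0.61 in RepB-/- against RepB+/-, with 12 of 12 lower. The 10 flanking genes had medians of -0.01 and -0.01, and 1 of 14378 windows of as many genes was as low between the RepB genotypes, while 218 were as high in RepB+/- against wild type. A copy gain in the RepB+/- cells may account for it, but the genes were chosen for the pattern, no DNA of the RepB+/- cells was analysed here and chromosome 16 shows 129 reads almost alone, so copy number and regulation cannot be told apart. Mfi2 was also lower in RepB-/- than in wild type (-2.55), which a gain in RepB+/- alone would not give.

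Allelic shares of MEF autosomes differed between the libraries, and copy number was set against allele calling. All 6 autosomes whose share moved by over 5 points also had a median log2 ratio of all reads beyond 0.1 in size, against 2 of the other 13 (Fisher's exact test over the chromosomes of these 2 libraries, two-sided p = 0.00103), which is what copy number that differs between the MEF lines would give. Allele calling or mapping would move reads between alleles and leave the total level, but the median size of the log2 ratio over the moved autosomes was 0.27, against 0.05 over the others. Even so, the alleles moved in opposite directions on chromosomes 1, 4, 7, 10 and 15. On chromosome 7 the median log2 ratio was 0.32 for 129 and -0.75 for CAST reads, while on chromosome 3 both rose (0.65 and 0.06). Allele calling as a part of the pattern is therefore not excluded. The series also holds input DNA and chromosome contact samples of the MEF lines, which could show copy number but were not analysed here, so a copy number difference is a hypothesis, and it may also enter the comparison of MEF expression. Whether it relates to the genotype was not tested.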
